A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

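The series maps ribonucleotides left in the genome of budding yeast (Saccharomyces cerevisiae) by the polymerases that replicate it. Per the labels' protocols, DNA was purified from cultures grown at 30 °C in rich medium to mid log phase or to saturation, sonicated to a mean length near 400 bp and ligated to an adapter, after which existing 3′ ends were blocked. The DNA was then nicked with recombinant RNase H2, which cuts at an embedded ribonucleotide, or with Nb.BtsI, an enzyme that nicks 1 strand at a fixed recognition site and serves as a calibration. Each new end was sequenced on an Ion Torrent chip, either a 318 chip or a P1 chip. The 20 libraries fall into 9 groups. RNase H2 libraries from log phase number 4 for the strain labelled POL, 5 for pol1-L868M, 3 for pol3-L612M, 2 for pol2-M644G and 2 for pol2-M644L. POL and pol1-L868M each have 1 RNase H2 library from stationary phase and 1 Nb.BtsI library from log phase.

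The labels list the libraries as separate samples of a strain and do not say that they came from separate cultures. A p-value therefore measures only the spread between these samples, which may be technical. Replicate numbers follow the order in which the samples are listed and pair nothing across strains. The genotype at RNH201, the catalytic subunit of RNase H2, is not stated in the labels, so counts inside that gene are reported first.

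The authors deposited 1 list of strand-specific positions per library, each with a raw count, and these counts were used as deposited, without any earlier normalization. Every listed position is 1 base wide and has a count of at least 1. Per the submitters' processing notes, the reads were processed with Bowtie2 2.0.0, SAMtools 0.1.18 and bedtools 2.16.2 on the sacCer3 build. Alignment filters, the treatment of reads that map to several places and of duplicates, and the rule that turns a read into a position are not given in the sources used here. Repeated sequence such as chromosome ends, Ty elements and the ribosomal DNA can therefore lose or share counts, and values there are treated as uncertain. The lists write chromosome XVI under another number, which was renamed. Gene names and positions came from a gene table of assembly R64, which has the coordinates of sacCer3, with 6431 nuclear genes, 6430 of them with a strand that their locus tag gives.

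Depth differed sharply between chips. The 13 libraries from the 318 chip hold 2326391 to 5657073 counts, and the 7 from the P1 chip hold 30446944 to 58669607. Densities in CPM are counts scaled to equal nuclear totals. The fits over origins, bins and genes were therefore also run with the 318 chip alone and with chip as a block, and single values per library with the 318 chip alone. Gene lists and correlations between profiles were run in neither way. Within groups, the chi-square statistic per degree of freedom over gene counts was 1.99 to 12.0 in the 10 pairs of libraries on the same chip and 4.65 to 23.8 in the 11 pairs on different chips, so no library was a copy of another. Counts come from sequenced reads without molecular identifiers in the labels, so intervals and floors cover counting error only.

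The strand and offset of a listed position were checked on the Nb.BtsI libraries without a genome sequence. Recognition sites of this enzyme on opposite strands cannot overlap except in 1 arrangement, so a bottom-strand nick should not lie 0 to 8 nt to the right of a top-strand nick, and should be enriched at 9 nt. Among 16143 positions with at least 30 counts in both libraries, 1 pair lay 0 to 8 nt to the right, 25 pairs lay 1 to 9 nt to the left and 14 pairs lay exactly 9 nt to the right, against a mean of 6.17 pairs per distance at 10 to 30 nt either side. The listed position was accordingly taken as the base 3′ of the nick on the strand given, and no shift was applied. The 16143 positions held 63.5% of nuclear Nb.BtsI counts in POL and 67.5% in pol1-L868M. The source of the other counts was not tested.

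Replication origins were called from the data, because no annotation of origins was used here. At each 100 bp step, the share of top-strand counts in the 10 kb to the right minus that in the 10 kb to the left, leaving 500 bp around the point, was taken from the summed pol2-M644G libraries. Local maxima of at least 0.1 that lay at least 7.5 kb apart were kept as origins. Results for pol2-M644G at these points are therefore not independent of the way the points were found. On simulated strands the caller found 206 of 217 placed points within 1 kb, among 221 calls. In separate simulated strands with no origins it called 6 points. Every placed point had the same sharp switch, larger than the smallest rise of 0.1 accepted. Strands were drawn from POL totals with counting error alone. The simulation therefore does not show how well weak points are found, or how many false points come from variation beyond counting error. Leading-strand counts are top-strand counts to the right of an origin plus bottom-strand counts to the left, over flanks from 500 bp to 5 kb, and lagging-strand counts are the rest.

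Strand ratios per origin were tested with edgeR's quasi-likelihood test, with the leading and the lagging count of each library as a pair, a coefficient per library and an effect of each strain on the ratio. Origins needed at least 10 counts in every library, and 313 of the 316 passed. The same model was fitted to top and bottom strands of 5 kb bins with at least 50 counts in every library (2343 bins). Gene density was tested with edgeR on the counts of both strands inside 6244 genes that passed edgeR's expression filter, with TMM normalization. That test concerns the share of a library's nuclear counts in a gene and not an absolute number of ribonucleotides. All 16 log-phase RNase H2 libraries entered each model and shared 1 estimate of spread. Adjusted p-values follow Benjamini-Hochberg with a threshold of 0.05. Single values per library were compared by exact two-sided permutation tests. They were adjusted over the comparisons of each measure, separately for those with POL and the direct ones. The mitochondrial and ribosomal DNA percentages were adjusted together as 1 measure. With 5 against 4 libraries such a test cannot go below 0.0159, with 3 against 4 below 0.0571, with 2 against 4 below 0.133, with 5 against 3 below 0.0357, and with 2 against 2 below 0.333.

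Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The lists were ribosomal protein genes, histones, glycolysis, replication, RNase H, strain markers, galactose, copy-variable genes, tRNA genes, snoRNA genes, genes within 20 kb of a chromosome end, genes within 5 kb of an origin and genes over 20 kb from every origin. Profiles along the chromosomes were compared through the log2 odds of the top strand in 5 kb bins with a pseudocount of 0.5, with 200 simulations of unchanged groups and with the POL libraries split between the mutants. Shares from single libraries carry exact 95% binomial intervals, and a count of 0 allows up to 3 counts.

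Groups, tests, gene lists, most alternatives and the rule for named items were fixed before the data were examined. The members of the lists by distance from an origin followed from the origins called in the data. By that rule the text names, for each comparison, up to 12 origins or genes with the largest change past the threshold and every mutant library on the same side of every POL library, up to 3 bins each way, up to 4 members of each gene list with the smallest p, and RNH201 always. The fixed list of named origins could not be matched to the called points and was left out, and the list of genes near a centromere, the identity of the incorporated base and the density at transcription factor motifs were not analysed here. Each model was first tested on simulated data for pol1-L868M against POL. A log2 change of 0.3 was recovered at 94.3% of changed origins, 86.9% of changed bins and 37.1% of changed genes, and a change of 0.6 at 100%, 100% and 85.7%. False calls numbered 2 of 213 origins, 9 of 2143 bins and 10 of 6044 genes.

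The alternatives were DESeq2, limma on log2 ratios with a pseudocount of 1, no filter on low counts, chip as a block, the 318 chip alone, only the 2 groups compared, all libraries thinned to equal depth, the 0.1% of positions with the highest counts left out, other flanks and bin sizes, other normalizations, the coding strand only, and leaving out each library in turn. Calling points from pol3-L612M or from the P1 pol2-M644G library, and keeping only points with well-covered flanks, were chosen after seeing the data. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.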

Results

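Ribonucleotides embedded in the genome, or Nb.BtsI sites in the calibration libraries, were mapped base by base and by strand in 20 libraries of budding yeast. The 5 strains were one labelled POL, whose label names no polymerase substitution, and mutants of the catalytic subunits of polymerase alpha (pol1-L868M), polymerase delta (pol3-L612M) and polymerase epsilon (pol2-M644G and pol2-M644L). The L868M, L612M and M644G substitutions are known to raise ribonucleotide incorporation and M644L to lower it, so that the strand bias of the mapped sites can tell which strand each polymerase makes. Each library held 2326391 to 5657073 counts on the 318 chip and 30446944 to 58669607 on the P1 chip. A value after ± is an SD over libraries for percentages and CPM, and a standard error for the log2 change of a single origin, bin or gene. Coordinates are those of sacCer3, and each 5 kb bin is named by its chromosome and first base. Nicking by Nb.BtsI and growth to stationary phase each gave 1 library per strain for POL and pol1-L868M, so those values have no replicates.

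RNH201, the gene of the catalytic subunit of RNase H2 (YNL072W, XIV 490317 to 491240), held 0 to 22 counts in each of the 20 libraries. Its mean density was 0.236 CPM in POL (n = 4), 0.361 in pol1-L868M (n = 5), 0.267 in pol3-L612M (n = 3), 0.130 in pol2-M644G (n = 2) and 0.191 in pol2-M644L (n = 2), while the median gene held 85.8 to 107.9 CPM. The Nb.BtsI libraries had 12 and 18 counts there. LEU2, a marker of leucine synthesis, was also nearly empty in every library, with 0 to 34 counts. URA3, HIS3, TRP1, LYS2, ADE2 and CAN1 were present throughout, from 107 counts in TRP1 to 26460 in LYS2. The silent mating gene HMRA1 held 72 to 2366 counts, while HMRA2 held 0 to 1, MATALPHA2 0 to 21, and MATALPHA1, HMLALPHA1 and HMLALPHA2 held 0. The mating-type loci hold near-identical copies, so these low counts do not show that a gene is absent.

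Replication origins appeared as points where the top-strand share of pol2-M644G counts rose from left to right. Calling them gave 316 origins, of which 168 lay inside a gene and 148 between genes, with a median distance of 27900 bp to the nearest other origin. The rise had a median of 0.453 at these points and ranged from 0.101 to 0.668, against 0.0854 at the 99th percentile of all points in POL. One origin lay 84 bp from TRP1 (IV 462600) and another 16 bp from HHF1, a histone H4 gene (II 255700). Averaged over origins, leading-strand counts made up 52.4% ± 0.298 of POL counts (n = 4) at 500 bp to 5 kb. In POL replicate 4, the P1 library of log-phase POL, a single position (XV 780641) holds 62983 counts. Its share of 52.8% is therefore uncertain, here and in the comparisons on the P1 chip below. Nb.BtsI nicks, which do not depend on ribonucleotides, gave 50.8% in POL (exact binomial 95% interval 50.686 to 50.897) and 50.8% in pol1-L868M (50.669 to 50.858).

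**Figure D1:**
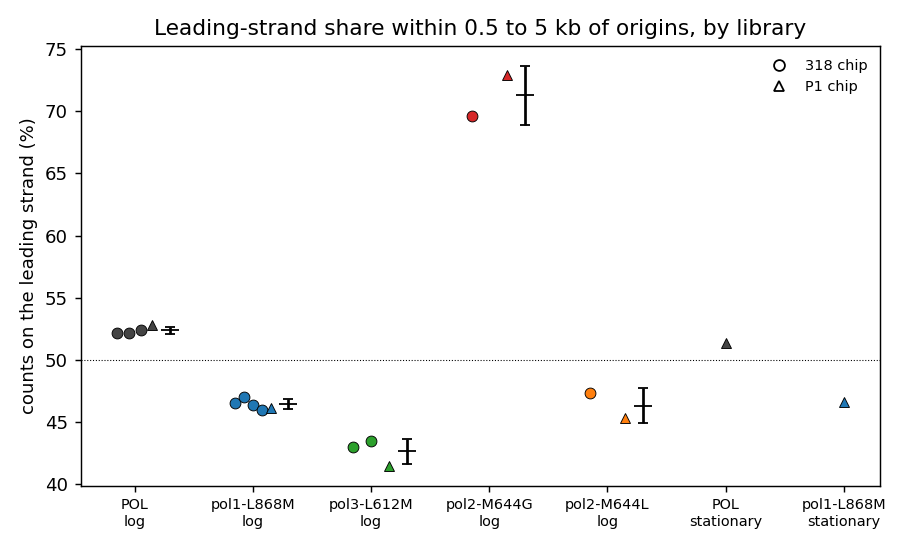
Leading-strand percentage of RNase H2 counts within 500 bp to 5 kb of 316 origins for each log-phase and stationary library, with circles for the 318 chip, triangles for the P1 chip and bars at the mean ± SD. The 2 pol2-M644G libraries lie at 69.6% and 73.0%, above log-phase POL at 52.2% to 52.8%, and the libraries of the other 3 mutants lie below POL.

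The pol1-L868M strain addressed where DNA made by polymerase alpha remains. Its ribonucleotides lay on the lagging strand more often than those of POL, with 46.4% ± 0.412 on the leading strand (n = 5) against 52.4% ± 0.298 (n = 4). The leading strand lost share at 263 of 313 origins, gained at 7 and did not pass the test at 43. The fall was largest at VII 484700, between BRP1 and YGL006W-A, by a log2 ratio of -0.66 ± 0.070 (adjusted p = 9.76e-19), and at XIII 287300, between ANY1 and the hexose transporter gene HXT2, by -0.64 ± 0.067. Other large falls were at V 94300 between SPF1 and ECM10 (-0.63 ± 0.072), XV 337200 inside DNL4, which encodes DNA ligase IV (-0.63 ± 0.070), and X 540200 beside HIT1 (-0.63 ± 0.069). The profile was deepest close to the origin, at 45.4% ± 0.721 between 0.75 and 1 kb, and stood at 48.3% ± 0.399 at 15 kb.

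Pooled over origins, the log2 ratio of leading to lagging counts in pol1-L868M minus that in POL was -0.34, and 5 of 5 pol1-L868M libraries lay below every POL library. The exact two-sided permutation p was 0.0159, the smallest for 5 against 4 libraries, and 0.0635 after adjustment over the 4 mutants. On the 318 chip alone the shares were 46.5% ± 0.444 (n = 4) and 52.3% ± 0.154 (n = 3), a log2 difference of -0.33 with an exact p of 0.0571, the smallest possible there, and on the P1 chip 46.2% and 52.8%. Along the chromosomes, the top-strand odds rose in 935 and fell in 896 of 2343 bins of 5 kb. They rose by 0.77 ± 0.073 in X_535001, 0.69 ± 0.069 in VII_480001 and 0.68 ± 0.073 in IV_905001, and changed by -0.76 ± 0.079 in XIII_190001, -0.68 ± 0.11 in XIII_195001 and -0.68 ± 0.070 in V_95001.

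Gene density in pol1-L868M lay below that of POL at 1 place. Of 6244 genes, 0 rose and 2 fell, with 64 at an unadjusted p under 0.05 in edgeR and 3 called by DESeq2. In this and every other comparison of gene density, edgeR gave fewer such genes than the share of 0.05 that chance alone would give. The test was therefore conservative, and a gene that did not pass is not shown to be unchanged. MET17, which encodes the sulfhydrylase that builds homocysteine (YLR303W, XII 732542 to 733876), changed by -1.04 ± 0.11 (adjusted p = 0.00016). YLR302C, a reading frame that overlaps its start (XII 732191 to 732553), changed by -0.94 ± 0.085 (adjusted p = 2.65e-05), and counts in the overlap belong to both. The third gene called by DESeq2 was the tRNA gene YNCL0037W beside them (XII 732090 to 732190), at -0.995 ± 0.20 in edgeR with an adjusted p of 0.26. Over XII 732001 to 734500, a segment chosen after its values were seen, pol1-L868M held 225 ± 15.8 CPM (n = 5), POL 453 ± 37.0 (n = 4), pol3-L612M 444 ± 43.5 (n = 3), pol2-M644G 475 ± 10.2 (n = 2) and pol2-M644L 473 ± 24.5 (n = 2). Counting the coding strand alone, which carries the strand bias itself, 175 genes passed.

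**Figure D2:**
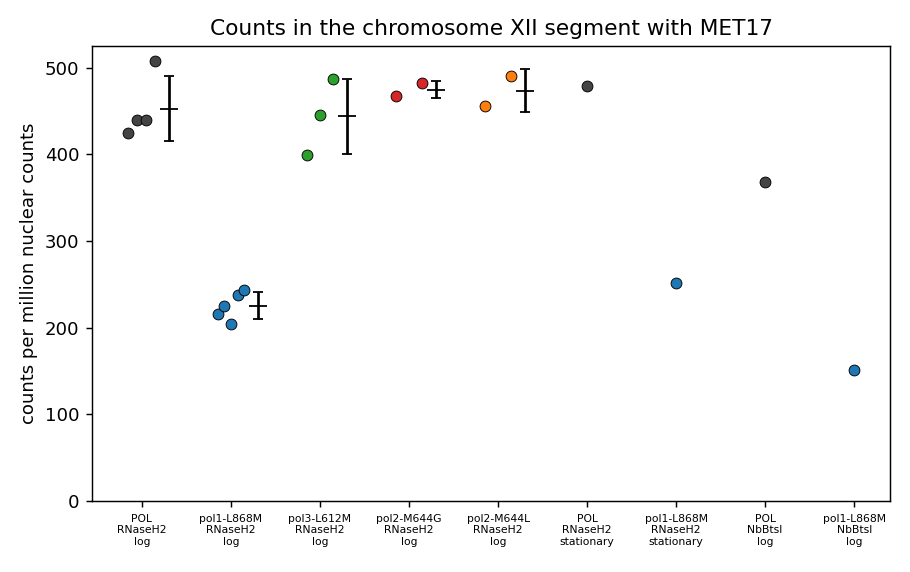
CPM, nuclear counts only, in the 2.5 kb segment of chromosome XII that holds MET17, for each library, with bars at the group mean and error bars of ±1 SD. The pol1-L868M RNase H2 libraries average 225 and those of POL 453, and the Nb.BtsI libraries stand at 151 and 368.

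Among the fixed gene lists in pol1-L868M, snoRNA genes, whose products guide rRNA modification, stood higher as a set, with a median log2 change of 0.18 over 76 genes (camera adjusted p = 1.53e-05 at the preset correlation and adjusted p = 0.873 with an estimated correlation). Examples were SNR61 at 1.25 ± 0.40 and SNR77 at 0.88 ± 0.40. Ribosomal protein genes had a median of 0.074 over 138 genes (adjusted p = 1.91e-04, and adjusted p = 0.873 with an estimated correlation), with RPS26A at 0.45 ± 0.15 and RPS10A at -0.20 ± 0.097. The 10 histone genes had a median of 0.20 (adjusted p = 6.61e-04, and adjusted p = 0.0724 with an estimated correlation), with HTB2 at 0.29 ± 0.12 and HHF1 at 0.31 ± 0.21. Genes near chromosome ends stood lower (183 genes, median -0.0093, adjusted p = 0.0493, and adjusted p = 0.873 with an estimated correlation), with ERG13 of sterol synthesis at -0.13 ± 0.068 and ERO1 at -0.11 ± 0.060. The 8 strain markers pointed down in the test (median -0.0014, mean -0.11, adjusted p = 0.00108, and adjusted p = 0.523 with an estimated correlation). In that list 1 gene fell, MET17, also when adjusted over the list alone, and it was the 1 member at an unadjusted p under 0.05, beside LYS2 at -0.068 ± 0.093. Not past the threshold were glycolysis (adjusted p = 0.699, TPI1 at 0.22 ± 0.17), replication (0.223, POL30 at -0.28 ± 0.10 and MCM6 at 0.057 ± 0.044) and RNase H (0.377, RNH203 at -0.27 ± 0.21). The same held for galactose (adjusted p = 0.752, GAL10 at -0.068 ± 0.064), tRNA (0.947), genes within 5 kb of an origin (0.0768, VMS1 at 0.22 ± 0.055 and SEC9 at 0.20 ± 0.057) and genes over 20 kb away (0.548, CKB2 at -0.22 ± 0.091). In the last of these the median and mean were above 0 and the test pointed down.

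Apart from MET17, edgeR called 0 genes on these lists in pol1-L868M over all genes tested. Adjusted over the list alone it added 1, the tRNA gene YNCL0037W. At an unadjusted p under 0.05 there were 3 ribosomal protein, 1 histone, 0 glycolysis, 1 replication, 0 RNase H, 1 marker, 0 galactose, 5 tRNA, 3 snoRNA and 1 chromosome-end gene, 30 genes near and 6 genes far from an origin. DESeq2 called MET17 and YNCL0037W.

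The pol3-L612M strain addressed where DNA made by polymerase delta lies. It had the lowest leading-strand share of the 5 strains, 42.6% ± 1.03 (n = 3) against 52.4% ± 0.298 in POL (n = 4). The leading strand lost share at 281 of 313 origins, gained at 6 and did not pass at 26. All 6 gains lay at points with a sparse flank. VII 484700 again fell, by -0.99 ± 0.080 (adjusted p = 1.87e-32), followed by IV 554600 inside VMS1, a gene of ribosome quality control (-0.93 ± 0.080), XIII 287300 beside HXT2 (-0.92 ± 0.076), XI 55600 inside EAP1, a translation repressor gene (-0.90 ± 0.079), and X 375200 inside LOH1 (-0.90 ± 0.072). The share was lowest at 41.8% ± 0.918 between 2.25 and 2.5 kb and was 45.7% ± 0.770 at 15 kb.

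Pooled over origins, the log2 ratio of pol3-L612M minus POL was -0.57, lower than every POL library in 3 of 3 libraries, with an exact two-sided permutation p of 0.0571, the smallest for 3 against 4, and 0.114 after adjustment. The shares were 43.2% ± 0.323 (n = 2) against 52.3% ± 0.154 (n = 3) on the 318 chip and 41.5% against 52.8% on the P1 chip. The top-strand odds rose in 1045 and fell in 1016 of 2343 bins, with 1.02 ± 0.079 in VII_480001, 0.99 ± 0.084 in XIII_280001, 0.95 ± 0.20 in IV_295001, -0.99 ± 0.089 in XIII_190001, -0.96 ± 0.077 in XV_340001 and -0.96 ± 0.078 in XVI_565001. Gene density passed the test at 0 of 6244 genes with edgeR and 0 with DESeq2 (27 and 25 at an unadjusted p under 0.05), and at 1950 on the coding strand alone. Both unadjusted counts lie below the share of 0.05 that chance alone would give, so the 0 does not show unchanged density.

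In pol3-L612M, 3 gene lists stood higher at the preset correlation. They were ribosomal protein genes (median 0.050, adjusted p = 0.00108, and adjusted p = 0.873 with an estimated correlation), tRNA genes (median 0.085, adjusted p = 0.00139, and adjusted p = 0.873 with an estimated correlation) and snoRNA genes (median 0.072, adjusted p = 0.0120, and adjusted p = 0.873 with an estimated correlation). RPL43B stood at 0.29 ± 0.16 and RPS10A at -0.22 ± 0.11, the tRNA genes YNCL0035C at 0.64 ± 0.23 and YNCG0017W at -0.65 ± 0.20, and SNR85 at 0.34 ± 0.19 and SNR73 at 0.55 ± 0.36. Not past the threshold were histones (adjusted p = 0.242, HTB2 at 0.13 ± 0.13), glycolysis (0.137, PFK1 at -0.066 ± 0.085), replication (0.564, MCM6 at 0.10 ± 0.050 and POL30 at -0.12 ± 0.12) and RNase H (0.699, RNH1 at 0.11 ± 0.13). Nor did strain markers pass (adjusted p = 0.377, CAN1, the arginine permease gene, at -0.12 ± 0.083 and URA3 at -0.091 ± 0.098), or galactose genes (0.550, GAL1 at -0.14 ± 0.11). By position, the adjusted p was 0.0768 for chromosome ends (AAD4 at -0.38 ± 0.18 and DLD3 at -0.21 ± 0.10), 0.242 for genes within 5 kb of an origin (GPX2 at -0.34 ± 0.11) and 0.359 for genes over 20 kb away (RCH1 at -0.19 ± 0.077 and URA5 at -0.20 ± 0.091). On these 12 lists edgeR called 0 genes, also adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 there were 6 tRNA genes, 1 chromosome-end gene, 9 genes near and 3 genes far from an origin, and 0 on each other list.

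The pol2-M644G strain addressed the product of polymerase epsilon. It was the only strain of the 5 with a large excess on the leading strand, 71.3% ± 2.37 (n = 2) against 52.4% ± 0.298 in POL (n = 4). The leading strand gained share at 303 of 313 origins, lost at 7 and did not pass at 3. The points were called from these same pol2-M644G libraries. The direction, the counts of origins and the p-values at single origins are therefore not independent of the calling. The rise was largest at III 273300 between YCR090C and KIN82, a gene of flippase regulation, by 1.58 ± 0.082 (adjusted p = 1.86e-76), at IV 1057800 between SUR2 and ATP5 (1.57 ± 0.083) and at XIII 689500 inside DML1 (1.55 ± 0.079). Large rises were also at XIV 450100 inside YPT53, a Rab GTPase gene (1.54 ± 0.081), and at XI 330200 inside TOA2, a subunit gene of TFIIA (1.54 ± 0.076). The share climbed from 52.4% ± 1.52 within 0.25 kb of the origin to 72.2% ± 2.32 at 1.5 to 1.75 kb and was 63.9% ± 1.56 at 15 kb.

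Pooled over origins, the log2 ratio of pol2-M644G minus POL was 1.18, higher than every POL library in 2 of 2 libraries, with an exact two-sided permutation p of 0.133, the smallest for 2 against 4, before and after adjustment. The shares were 69.6% against 52.3% ± 0.154 (n = 3) on the 318 chip and 73.0% against 52.8% on the P1 chip. At points called from pol3-L612M instead, the log2 difference was 1.26. The 7 points that lost share, among them I 206100 in FLO1, IV 527000 in KRS1 and XII 489800 in YLR162W near the ribosomal DNA, changed by -1.43 to -0.94, and each has sparse counts beside it. The top-strand odds rose in 1078 and fell in 1103 of 2343 bins, with 1.97 ± 0.39 in XV_235001, 1.79 ± 0.13 in XIV_95001, 1.70 ± 0.088 in XIV_450001, -1.83 ± 0.090 in IX_65001, -1.73 ± 0.099 in IV_800001 and -1.65 ± 0.24 in IX_390001. Gene density passed at 0 of 6244 genes with edgeR and 0 with DESeq2 (215 and 256 at an unadjusted p under 0.05), and at 4398 on the coding strand alone. Here too both unadjusted counts lie below a share of 0.05, so the 0 does not show unchanged density.

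**Figure D3:**
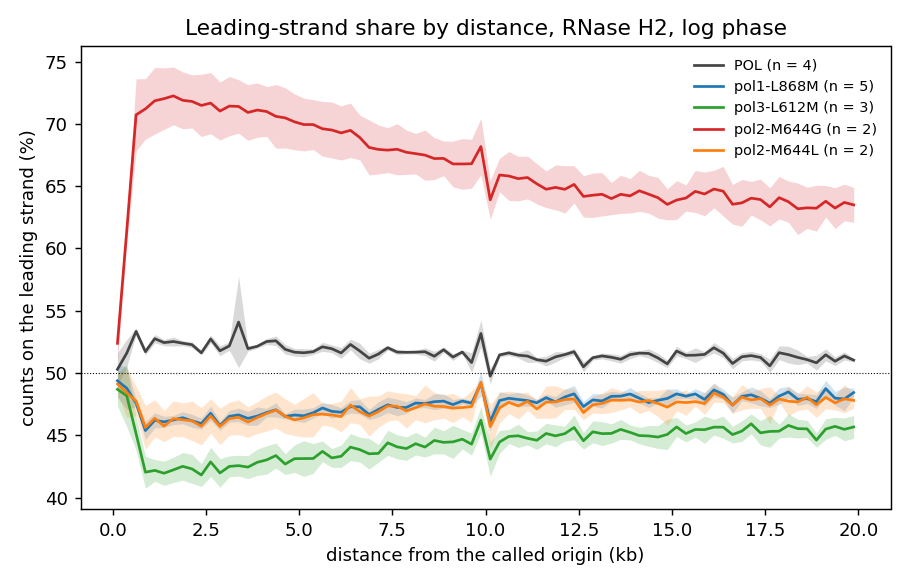
Leading-strand percentage of RNase H2 counts against the distance from the origin in kb, averaged over origins in 0.25 kb steps, in log phase, with lines for the group means and bands of ±1 SD. The pol2-M644G line peaks at 72.2% and the pol3-L612M line is lowest at 41.8%, while pol1-L868M and pol2-M644L reach 45.4% and 45.6% within 1 kb.

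In pol2-M644G, gene density differed with the distance from origins at the preset correlation. The origins that fill these lists were called from the same pol2-M644G libraries, so this result is not independent of the lists. Genes over 20 kb from every origin stood lower (1024 genes, median -0.059, adjusted p = 1.35e-05, and adjusted p = 0.0724 with an estimated correlation), with EIS1 at -0.26 ± 0.070, STP4 at -0.45 ± 0.13 and MIP1, the mitochondrial DNA polymerase gene, at -0.24 ± 0.077. Genes within 5 kb stood higher (1642 genes, median 0.035, adjusted p = 0.0120, and adjusted p = 0.0927 with an estimated correlation), with SAP4 at 0.26 ± 0.076 and SHQ1 at 0.25 ± 0.077, while PMA1, the plasma membrane proton pump gene, stood at -0.37 ± 0.10. Ribosomal protein genes stood higher (median 0.091, adjusted p = 2.20e-04, and adjusted p = 0.873 with an estimated correlation), with RPS26A at 0.61 ± 0.18 and RPL19B at 0.29 ± 0.11. Not past the threshold were histones (adjusted p = 0.962, HTB1 at 0.25 ± 0.15), glycolysis (0.132, PYK2 at -0.22 ± 0.14), replication (0.599, MCM6 at 0.16 ± 0.056 and MCM3 at -0.26 ± 0.13) and RNase H (0.945, RNH202 at 0.16 ± 0.088). Strain markers (adjusted p = 0.137, TRP1 at -0.22 ± 0.11 and CAN1 at -0.15 ± 0.093) and galactose genes (0.947, GAL7 at 0.25 ± 0.14 and GAL4 at 0.11 ± 0.065) did not pass either. Nor did tRNA genes (adjusted p = 0.564, YNCC0005W at -1.01 ± 0.23), snoRNA genes (0.102, SNR61 at 1.26 ± 0.45) and chromosome ends (0.268, PAU10, a gene with near-identical copies, at -1.44 ± 0.50 and ARR2 at 0.39 ± 0.14). The median was below 0 while mean and test pointed up for galactose and replication genes, and median and mean were below 0 while the test pointed up for RNase H genes. On these 12 lists edgeR called 0 genes, also adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 there were 3 ribosomal protein, 2 replication, 6 tRNA, 1 snoRNA and 7 chromosome-end genes, 57 genes near and 54 genes far from an origin, and 0 on each other list.

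The pol2-M644L strain addressed what remains when polymerase epsilon incorporates fewer ribonucleotides. Its leading-strand share was 46.3% ± 1.39 (n = 2), below the 52.4% ± 0.298 of POL (n = 4). The leading strand lost share at 270 of 313 origins, gained at 7 and did not pass at 36. All 7 gains lay at points with a sparse flank. Falls were largest at X 375200 inside LOH1 (-0.62 ± 0.078, adjusted p = 7.89e-13), XIII 287300 beside HXT2 (-0.61 ± 0.084), X 613200 inside YJR098C (-0.60 ± 0.081), V 94300 between SPF1 and ECM10 (-0.60 ± 0.091) and III 74600 between HBN1 and FRM2 (-0.59 ± 0.090). VII 569100 changed by -0.62 ± 0.22 (adjusted p = 0.00699), and without POL replicate 3 it stood at -0.48 and no longer passed. The share was lowest at 45.6% ± 1.76 between 0.75 and 1 kb and was 47.7% ± 0.705 at 15 kb.

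Pooled over origins, the log2 ratio of pol2-M644L minus POL was -0.35, lower than every POL library in 2 of 2 libraries, with an exact two-sided permutation p of 0.133, the smallest for 2 against 4, before and after adjustment. The shares were 47.3% against 52.3% ± 0.154 (n = 3) on the 318 chip and 45.4% against 52.8% on the P1 chip. The top-strand odds rose in 901 and fell in 880 of 2343 bins, 1781 in all, and 971 passed without pol2-M644L replicate 2. They changed by 0.72 ± 0.088 in X_535001, 0.63 ± 0.091 in IV_550001, -0.66 ± 0.098 in XIII_200001 and -0.63 ± 0.085 in XVI_565001. The call at IV_295001 (0.75 ± 0.22) was lost with only the 2 groups compared, at 0.77, and without pol2-M644L replicate 2, at 0.73. The call at II_1, the left end of that chromosome (-0.63 ± 0.26), was lost on the 318 chip alone at -0.65, and without POL replicate 2 at -0.47, POL replicate 3 at -0.57 or pol2-M644L replicate 2 at -0.43.

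Of 6244 genes, 0 rose and 1 fell in pol2-M644L, with 25 at an unadjusted p under 0.05 in edgeR and 1 called by DESeq2. The gene was YHL050C, a repeated reading frame at a chromosome end (VIII 445 to 3311), whose counts are uncertain because copies exist elsewhere. It changed by -3.88 ± 0.50 (adjusted p = 0.00439), stood at -2.95 on the 318 chip alone with an adjusted p of 0.080, and did not pass without pol2-M644L replicate 2, at -2.75. Over VIII 1 to 5500, chosen after its values were seen, pol2-M644L held 3.12 ± 2.85 CPM (n = 2), POL 48.9 ± 7.28 (n = 4), pol1-L868M 44.7 ± 5.97 (n = 5), pol3-L612M 51.9 ± 9.02 (n = 3) and pol2-M644G 45.7 ± 6.26 (n = 2). On the coding strand alone 1 gene passed in pol2-M644L.

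Among the lists in pol2-M644L, snoRNA genes stood higher (median 0.074, adjusted p = 0.0149, and adjusted p = 0.873 with an estimated correlation), with SNR35 at 0.44 ± 0.24 and SNR4 at -0.31 ± 0.15. Not past the threshold were ribosomal protein genes (adjusted p = 0.548, RPS26A at 0.30 ± 0.18 and RPL32 at -0.21 ± 0.13), histones (0.133, HTB2 at -0.19 ± 0.15 and HTB1 at -0.18 ± 0.16) and glycolysis (0.377, TPI1 at -0.19 ± 0.21). Replication (adjusted p = 0.932, RFC1 at 0.083 ± 0.069 and MCM6 at 0.066 ± 0.056) and RNase H genes (0.550, RNH202 at 0.10 ± 0.088) did not pass, and neither did strain markers (0.897, URA3 at -0.098 ± 0.11 and HIS3 at -0.15 ± 0.24). The adjusted p was 0.550 for galactose (GAL4 at 0.073 ± 0.065) and 0.268 for tRNA genes (CDC65 at -0.57 ± 0.25 and YNCE0016C at -0.66 ± 0.26). By position, it was 0.962 for chromosome ends (ARR3, an arsenite exporter gene, at 0.20 ± 0.11), 0.328 for genes within 5 kb of an origin (AIM21 at -0.21 ± 0.084) and 0.242 for genes over 20 kb away (BNA4 at 0.23 ± 0.090 and the checkpoint kinase gene DUN1 at -0.20 ± 0.091). The median was above 0 while mean and test pointed down for strain markers, median and mean were below 0 while the test pointed up for replication genes, and the mean alone was below 0 for chromosome ends. YHL050C was the 1 gene called, on the lists of chromosome ends and of genes far from origins, and was also called there when adjusted over the list alone and by DESeq2. On the other 10 lists edgeR called 0 genes, also adjusted over the list alone, and DESeq2 called 0. At an unadjusted p under 0.05 there were 1 ribosomal protein, 3 tRNA and 1 chromosome-end gene, 8 genes near and 3 genes far from an origin, and 0 on each other list. Of the copy-variable genes, 2 of 9 were measured, too few for a test in any strain.

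pol1-L868M and pol3-L612M, the mutants of polymerases that work on the lagging strand, were compared directly. Leading-strand share was 46.4% ± 0.412 (n = 5) against 42.6% ± 1.03 (n = 3), and was higher in pol1-L868M at 246 of 313 origins, lower at 6 and not past the threshold at 61. The difference was largest at IV 806600 beside HSP42, a small heat shock protein gene (0.40 ± 0.080, adjusted p = 1.41e-05), X 298900 beside SMC3, a cohesin subunit gene (0.40 ± 0.068), XIV 412500 beside RPC19 (0.38 ± 0.069) and XII 888900 inside IKI3 (0.38 ± 0.070). Pooled over origins it was 0.22, higher than every pol3-L612M library in 5 of 5, with an exact two-sided permutation p of 0.0357, the smallest for 5 against 3, and 0.0714 after adjustment over the 2 direct comparisons. On the 318 chip the shares were 46.5% ± 0.444 (n = 4) and 43.2% ± 0.323 (n = 2), a log2 difference of 0.19 with an exact p of 0.133, the smallest possible there, and on the P1 chip 46.2% and 41.5%.

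The top-strand odds of pol1-L868M were higher than those of pol3-L612M in 819 and lower in 867 of 2343 bins, 1686 in all, and 949 passed without pol3-L612M replicate 3. XIV_770001 stood at 0.47 ± 0.087, IV_535001 at -0.49 ± 0.10, VII_1055001 at -0.48 ± 0.080 and XII_20001 at -0.48 ± 0.077. VIII_550001 (0.53 ± 0.14) lost its call without pol3-L612M replicate 3, at 0.35, and VIII_555001 (0.50 ± 0.16) without pol1-L868M replicate 5, at 0.22, on the 318 chip alone, at 0.31, or with libraries thinned to equal depth, at 0.23. Of 6244 genes, 0 were higher and 2 lower in pol1-L868M, MET17 (-1.004 ± 0.12, adjusted p = 0.000685) and YLR302C (-0.92 ± 0.091, adjusted p = 0.000116), with 31 at an unadjusted p under 0.05, 2 called by DESeq2 and 2 on the coding strand alone. Among the lists, histone genes stood higher in pol1-L868M (median 0.12, adjusted p = 0.0344, and adjusted p = 0.248 with an estimated correlation). There tRNA genes stood lower (median -0.037, adjusted p = 3.02e-04, and adjusted p = 0.807 with an estimated correlation). The test of strain markers also pointed down, with MET17 the 1 gene called, also adjusted over the list alone (adjusted p = 0.0208, and adjusted p = 0.631 with an estimated correlation), though their median was 0.023. The other 9 lists had adjusted p-values of 0.0944 for snoRNA genes or more, and chromosome-end genes had a median and mean above 0 while the test pointed down.

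pol2-M644G and pol2-M644L, different substitutions of the same residue, lay on opposite sides of POL, at 71.3% ± 2.37 and 46.3% ± 1.39 on the leading strand (n = 2 each). The share was higher in pol2-M644G at 303 of 313 origins and lower at 7. Because the origins were called from the pol2-M644G libraries, these counts and the p-values below are not independent of the calling. Large differences were at II 63500 between YBL086C and BOI1, a gene of polar growth (2.06 ± 0.10, adjusted p = 8.51e-88), V 94300 between SPF1 and ECM10 (2.04 ± 0.10), X 684400 between MET5 and IML1 (2.00 ± 0.10) and XV 167500 between ATG34 and ATG19, genes of selective autophagy (2.00 ± 0.10). Pooled over origins the log2 difference was 1.53, with an exact two-sided permutation p of 0.333, the smallest for 2 against 2. The shares were 69.6% and 47.3% on the 318 chip and 73.0% and 45.4% on the P1 chip.

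The top-strand odds of pol2-M644G were higher in 1087 and lower in 1110 of 2343 bins, with 2.19 ± 0.14 in XIV_95001, 2.12 ± 0.11 in XI_620001, 2.10 ± 0.11 in IV_755001, -2.11 ± 0.099 in IX_65001, -2.04 ± 0.10 in XIII_795001 and -2.03 ± 0.14 in X_195001. Of 6244 genes 1 was higher and 0 lower, YHL050C (3.73 ± 0.52, adjusted p = 0.0125), with 27 at an unadjusted p under 0.05 and 1 called by DESeq2. That call was lost on the 318 chip alone (2.80), with libraries thinned to equal depth (2.90), with the 2 groups alone (3.80), and without pol2-M644G replicate 1 (3.53), pol2-M644G replicate 2 (3.94) or pol2-M644L replicate 2 (2.59). On the coding strand alone 4806 genes passed. Ribosomal protein genes stood higher in pol2-M644G (median 0.072, adjusted p = 2.27e-05, and adjusted p = 0.781 with an estimated correlation), as did genes within 5 kb of an origin (median 0.026, adjusted p = 0.0317, and adjusted p = 0.133 with an estimated correlation). Genes over 20 kb from every origin stood lower (median -0.043, adjusted p = 4.38e-06, and adjusted p = 0.0502 with an estimated correlation). The origins behind both lists by distance were called from the pol2-M644G libraries themselves. The other 9 lists had adjusted p-values of 0.0830 for strain markers or more, and replication genes had a median below 0 with mean and test above it.

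Changes along the chromosomes were set against each other over 2343 bins, which are not independent replicates. The changes of pol1-L868M and pol3-L612M correlated at a Pearson r of 0.981 (Spearman 0.980), those of pol1-L868M and pol2-M644L at 0.973 (0.969) and those of pol3-L612M and pol2-M644L at 0.979 (0.973). Each of the 3 ran against pol2-M644G, at -0.875 (-0.865) for pol1-L868M, -0.905 (-0.888) for pol3-L612M and -0.912 (-0.894) for pol2-M644L. All share the POL libraries, and simulated unchanged groups gave an r of 0.486 for pol1-L868M with pol3-L612M and between 0.334 and 0.429 for the other pairs. Split POL libraries gave 0.946, 0.918 and 0.945 for the positive pairs and -0.870, -0.904 and -0.906 for the negative ones. The covariances were 0.172, 0.101, 0.174, -0.298, -0.530 and -0.315 in the same order, against 0.0033 in the simulations. The same sign was found in 96.9%, 95.3% and 95.9% of bins for the positive pairs and in 11.3%, 10.3% and 9.05% for the negative ones.

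**Figure D4:**
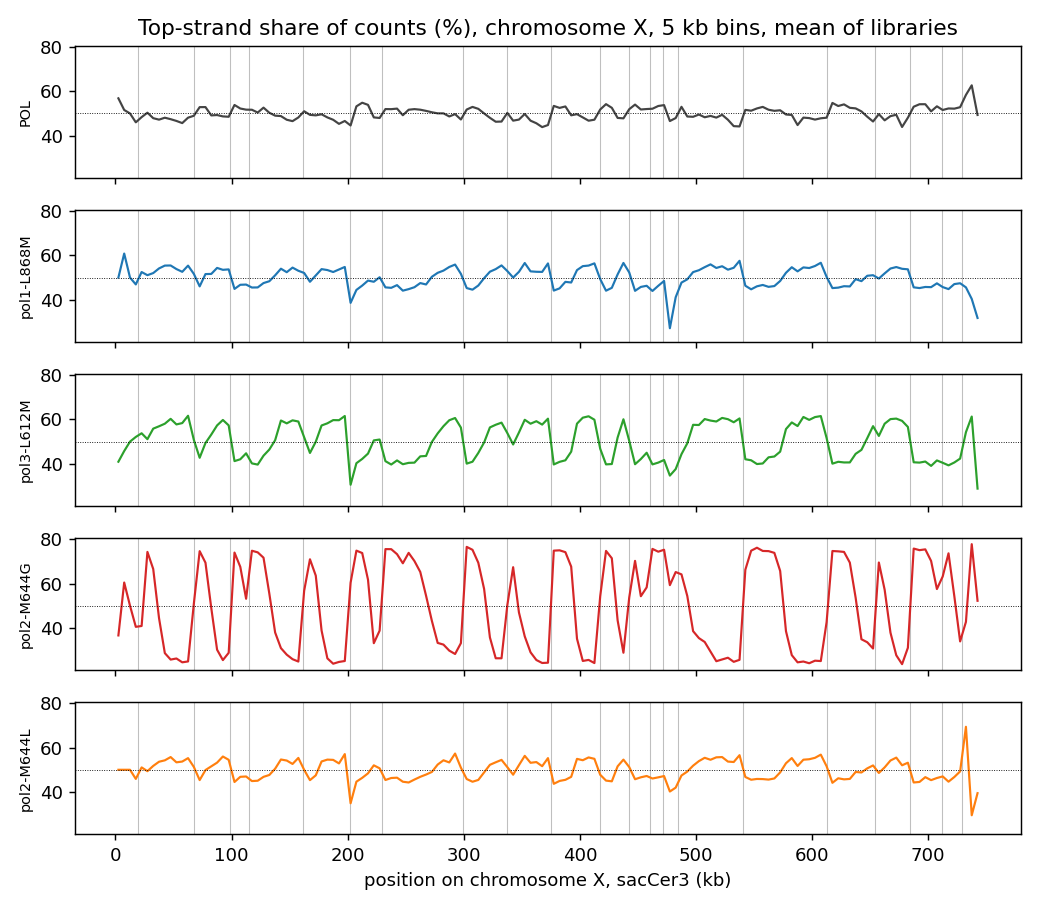
Mean top-strand percentage of RNase H2 counts in 5 kb bins along chromosome X for each strain, with grey vertical lines at the called origins. At X 375200 and X 540200 the pol2-M644G line rises from left to right, where the pol1-L868M, pol3-L612M and pol2-M644L lines fall.

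Growth phase was compared in POL and pol1-L868M with 1 stationary library each, so no test was made. The leading-strand share was 51.4% in stationary POL (exact binomial 95% interval 51.352 to 51.408) and 52.2% to 52.8% in log phase. In stationary pol1-L868M it was 46.6% (46.622 to 46.676), within the 46.0% to 47.0% of log phase. Both stationary libraries were on the P1 chip, where the log-phase library stood at 52.8% in POL and 46.2% in pol1-L868M. The 52.8% is uncertain, because a single position of that library holds 62983 counts. At points called from pol3-L612M instead, the same POL libraries stood at 52.3% in log phase and 51.2% in stationary phase. The MET17 segment held 479 CPM in stationary POL and 252 in stationary pol1-L868M.

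Count density near origins, which depends on ribonucleotide incorporation as well as on DNA copy number, was set against that far from them. The log2 ratio was 0.12 ± 0.0056 in POL (n = 4), 0.15 ± 0.023 in pol1-L868M (n = 5), 0.15 ± 0.018 in pol3-L612M (n = 3), 0.19 ± 0.0059 in pol2-M644G (n = 2) and 0.13 ± 0.0047 in pol2-M644L (n = 2). In stationary cultures it was 0.052 and 0.064, and with Nb.BtsI 0.084 and 0.10, for POL and pol1-L868M. The exact permutation p was 0.0794 for pol1-L868M, 0.0571 for pol3-L612M, 0.133 for both pol2 mutants, and 0.133 for each after adjustment over the 4 mutants, so none passed. The direct comparisons gave 0.893 and 0.333.

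**Figure D5:**
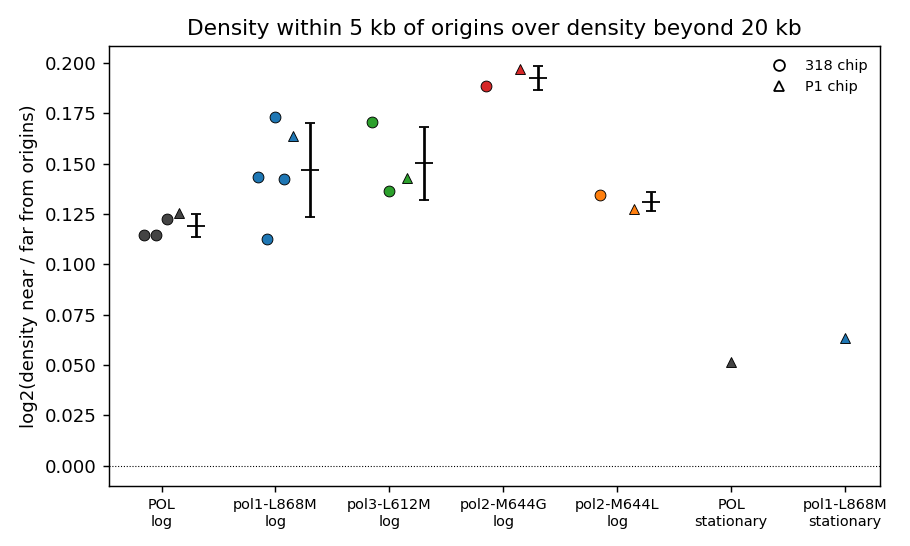
Log2 ratio of the count density within 5 kb of origins to that beyond 20 kb for each RNase H2 library, with circles for the 318 chip, triangles for the P1 chip and bars at the mean ± SD. The pol2-M644G libraries average 0.19 and those of POL 0.12, and the stationary libraries stand at 0.052 and 0.064.

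Mitochondrial DNA took 1.93% ± 0.113 of counts in POL (n = 4), 1.77% ± 0.193 in pol1-L868M (n = 5), 1.14% ± 0.541 in pol3-L612M (n = 3), 1.17% ± 0.0636 in pol2-M644G (n = 2) and 1.37% ± 0.445 in pol2-M644L (n = 2). The lowest exact permutation p for these percentages was 0.0571, and 0.356 after adjustment. The ribosomal DNA genes took 0.0213% ± 0.0127, 0.0289% ± 0.0179, 0.0414% ± 0.0294, 0.0106% ± 0.00563 and 0.0188% ± 0.0144 in the same order, with no comparison past the threshold. These means mix chips in different proportions. The percentage was lower on the P1 chip than in every 318 library of the same strain, at 0.00436% against 0.0269% ± 0.00703 in POL (n = 3 on the 318 chip), 0.00726% against 0.0344% ± 0.0151 in pol1-L868M (n = 4) and 0.00975% against 0.0572% ± 0.0151 in pol3-L612M (n = 2). In the pol2 mutants it was 0.00666% against 0.0146% in pol2-M644G and 0.00860% against 0.0290% in pol2-M644L. Nb.BtsI libraries held 0.678% and 0.699% mitochondrial and 0.237% and 0.378% ribosomal DNA counts for POL and pol1-L868M. In genes, the coding strand held 49.7% ± 0.609 of POL counts and 49.98% to 50.5% on average in the mutants.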

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

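The tests of the MET17 segment, of the points with opposite direction and of the chip, and the splits of libraries for the origin counts, were chosen only after the results were seen, and the splits for bins and genes were not.

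In pol1-L868M the segment of chromosome XII with MET17 (XII 732001 to 734500) held an RNase H2 density 2.01 times lower than in POL. The Nb.BtsI libraries differed there too, with 1354 counts in POL and 700 in pol1-L868M. Nb.BtsI nicks follow DNA and not ribonucleotides, though part of the counts of these libraries lay outside the recurrent nick positions. The log2 ratio was 1.28 (95% interval 1.15 to 1.42), which 0 of 4600 windows of the same length reached, against a 95th percentile of 0.41. The lower bound of 1.15 lies above the windows' median of 0.030 and argues against fewer ribonucleotides per DNA copy, and MET17 stood at -0.9996 with the 318 chip alone (adjusted p = 0.00144), which argues against the chip. A difference in DNA copy number of the segment between the strains may account for the pattern, as a hypothesis found and tested on the same data. The median window of this length held 215 CPM in POL and 213 in pol1-L868M, while the segment held 453 and 225. The segment thus stood near that level in pol1-L868M and above it in POL. It held 444 in pol3-L612M, 475 in pol2-M644G and 473 in pol2-M644L, near the POL value. How the strains were built, which stays open, was not tested.

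At 7 called points the pol2-M644G change ran opposite to the other origins. All 7 have sparse mapped counts beside the point, with a flank under 50% of the median POL flank. Of the 279 points with both flanks covered, 0 were called in the opposite direction, while of the 34 tested points with a sparse flank 7 were (Fisher's exact test, two-sided p = 9.86e-08). Sparse mapped counts beside the point may therefore have a part in the pattern. They do not set the direction alone, since 26 of the 34 were called in the direction of the other origins, and no biological explanation was tested.

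In each of the 5 strains the strand bias of the P1 library lay farther from 50% than the mean of the 318 libraries, by factors of 1.24 for POL, 1.09 for pol1-L868M, 1.26 for pol3-L612M, 1.17 for pol2-M644G and 1.74 for pol2-M644L. In pol1-L868M the P1 library, at 46.2%, lay within the 318 libraries, from 46.0% to 47.0%, and so did not stand apart from them. The POL factor is uncertain, because a single bottom-strand position of its P1 library, XV 780641, holds 62983 counts. No factor was computed without that position. At points called from pol3-L612M instead, POL replicate 4 stood at 52.3%, within the 52.3% to 52.6% of the POL libraries on the 318 chip. A larger share of counts without strand information on the 318 chip could give 1 factor in every strain. The highest factor was 1.59 times the lowest with a spread of 0.293, which takes in the bound of 1.5 set for equal factors, so this stays open with 1 P1 library per strain. Depth goes with the chip and cannot be told apart from it, and differences between the cultures were not tested.

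Other splits of the same libraries bear on chance. Of the 126 possible for pol1-L868M and POL, 100 were drawn for origins and genes and 40 for bins, and of the 56 for pol1-L868M and pol3-L612M, 40 were drawn for bins. For origins, 1 of 100 splits of the pol1-L868M and POL libraries gave 270 or more calls (highest other 232). Likewise 1 of 35 splits for pol3-L612M and POL gave 287 (highest other 261), and 1 of 56 for pol1-L868M and pol3-L612M gave 252 (highest other 1). In each case the 1 was the real split, which argues against chance among the splits drawn. It does not exclude chance. Not all splits of pol1-L868M and POL were drawn, and the exact permutation tests of the pooled strand ratio did not pass after adjustment. For 5 kb bins, 1 of 40 splits gave 1831 or more for pol1-L868M and POL (highest other 1339). For pol3-L612M and POL 1 of 35 gave 2061 (highest other 1826), and for pol1-L868M and pol3-L612M 1 of 40 gave 1686 (highest other 1). Each was again the real split, which argues against chance only among the splits drawn. For genes, 4 of 100 splits gave the 2 calls of pol1-L868M and POL or more. That share is under 0.05 among the splits drawn, though those not drawn could move it past. The highest other split gave 949, so the count alone does not exclude chance. That split puts both P1 libraries on the same side, with pol1-L868M replicates 2 and 3 and POL replicate 2, which are not on that chip. A single split cannot show a structure of the samples by chip. How the number of genes varies with the side of the P1 libraries was not tested. With chip as a block the real split gave 2 genes. For pol1-L868M and pol3-L612M, 5 of 56 splits gave 2 genes or more, so chance cannot be excluded by the count, the highest other split gave 1048 with both P1 libraries together, and the blocked value was 2 genes. For pol3-L612M and POL the real count was 0, which all 35 of 35 splits reach by definition (highest other 0), so the splits say nothing about chance.

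Within groups of 4 or 5 libraries, 19 of 358 tested values stood apart from the rest of their group, against 17.9 by chance alone at 1 in 20. Total counts did so by design of the chip, with 30446944 in POL replicate 4 and 51060856 in pol1-L868M replicate 5. The position with the most counts took 0.207% of POL replicate 4, against at most 0.00506% in the other POL libraries, and 0.0200% of pol1-L868M replicate 1, against at most 0.00747% in its group. The log2 ratio of leading over lagging counts stood apart at IV 1057800 in POL replicate 4 (0.21), VII 569100 in POL replicate 3 (0.94), X 417500 in POL replicate 1 (0.33) and II 63500 in pol1-L868M replicate 3 (-0.47). CPM stood apart in POL for GAL4 (295.7, replicate 4), the tRNA gene YNCG0004W (5.42, replicate 3), SHQ1 (123, replicate 4) and STP4 (147, replicate 3). In pol1-L868M they did so for RPL41A (7.52, replicate 4), HHF1 (14.2, replicate 5), TRP1 (115, replicate 5), GAL7 (76.5, replicate 3), ERO1 (124, replicate 3), YMR175W-A (10.4, replicate 2) and the tRNA gene YNCJ0013C (5.20, replicate 5).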

How the results depend on the processing

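The origin sets called from pol3-L612M or from the deep pol2-M644G library and the restriction to covered flanks were alternatives chosen after seeing the data, and the other alternatives were not. Over all alternatives except leaving out a library, 268 values of whole comparisons stayed the same, 24 counts or correlations moved, 6 changed sign, 2 lost and 1 gained the threshold. A tested value stayed the same if it kept its direction and its side of the threshold. A count of origins, bins or genes did so within a factor of 1.5 of the main count, whichever of them passed. Among single origins, bins, genes and gene lists, 2951 stayed, 66 changed sign, 41 gained and 20 lost the threshold. The pooled strand ratio kept its direction in all 8 alternatives, from -0.39 to -0.28 for pol1-L868M, -0.65 to -0.48 for pol3-L612M, 1.03 to 1.26 for pol2-M644G, -0.40 to -0.28 for pol2-M644L, 0.19 to 0.26 for pol1-L868M against pol3-L612M and 1.32 to 1.66 for pol2-M644G against pol2-M644L. Origins past the threshold numbered 244 to 283, 261 to 296, 277 to 313, 240 to 282, 189 to 268 and 278 to 312 in the same order over 12 alternatives that tested 279 to 316 points. Of the 240 points called from pol3-L612M instead, 233, 237, 240, 235, 230 and 239 passed. The 237 and the 230 involve pol3-L612M and are not independent of the way these points were found. No paired analysis was made, because the labels number no replicates across strains, and the run numbers in the sample titles were not used as blocks. The fixed named origins, genes near a centromere, a mapping-quality filter, the identity of the base and the density at transcription factor motifs were not run. With every library thinned to the depth of the shallowest, genes past the threshold against POL numbered 2 for pol1-L868M, 0 for pol3-L612M, 0 for pol2-M644G and 1 for pol2-M644L, as at full depth. Bins of 5 kb past it numbered 1707, 1986, 2131 and 1455, against 1831, 2061, 2181 and 1781 at full depth.

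With the 318 chip alone the pooled ratio was -0.33 for pol1-L868M against POL and 0.19 for pol1-L868M against pol3-L612M, and both exact p-values stopped at the smallest that fewer libraries allow. On that chip YHL050C no longer passed, so the gene counts of pol2-M644L against POL and of pol2-M644G against pol2-M644L were 0, and so was the latter with only the 2 groups or with libraries thinned to equal depth. Also on that chip, the mitochondrial percentage of pol2-M644G minus pol2-M644L was 0.077, and the ribosomal DNA percentage of pol2-M644L minus POL was 0.0021. Leaving out the highest 0.1% of positions gave a difference in density near origins of 0.028 for pol1-L868M with an unadjusted exact permutation p of 0.0159, and 0.0076 for pol1-L868M minus pol3-L612M. It turned the ribosomal DNA difference to -0.00057 for pol1-L868M and -0.0016 for pol3-L612M against POL, and to 0.0010 between these mutants. The cause of these changes was not tested.

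Split POL libraries gave profile correlations of 0.946 for pol1-L868M with pol3-L612M, 0.918 for pol1-L868M with pol2-M644L and 0.945 for pol3-L612M with pol2-M644L, where each change rests on fewer POL libraries and none are shared. Covariances were then 0.169, 0.0976 and 0.171, against 0.172, 0.101 and 0.174 with all POL libraries and 0.0033 in simulated unchanged groups that share them. How much of the lower r comes from fewer libraries was not tested. Bins of 2 kb, which are more numerous, gave 4050 calls for pol1-L868M, 4908 for pol3-L612M, 5324 for pol2-M644G, 3824 for pol2-M644L, 3096 for pol1-L868M against pol3-L612M and 5382 for pol2-M644G against pol2-M644L. Bins of 10 kb, which are fewer, gave 979, 1061, 1103, 924, 880 and 1121. With an estimated correlation between genes, 0 of the 12 gene list and mutant pairs past the threshold remained past it.

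Counting the coding strand alone lets the strand bias into gene density by construction, and 175 genes passed for pol1-L868M, 1950 for pol3-L612M, 4398 for pol2-M644G and 4806 for pol2-M644G against pol2-M644L. For pol2-M644L and for pol1-L868M against pol3-L612M the counts were 1 and 2, as with both strands (890 and 473 at an unadjusted p under 0.05), although the pooled strand ratio of pol2-M644L, -0.35, was close to that of pol1-L868M, -0.34. The cause of this difference was not tested. The sign of 51 named genes turned under that setting. In pol1-L868M the log2 changes were HTA2 -0.17, TDH3 -0.18, ENO2 -0.11, LYP1 -0.14, GAL10 0.11, GAL2 -0.12 and SNR4 0.10. In pol3-L612M the log2 changes were HHT1 -0.61, TDH3 -0.30, ENO2 -0.29, POL30 0.24, PRI1 0.13, GAL10 0.30, SUF1 -0.21, DLD3 0.11 and YAL067W-A 0.023. In pol2-M644G the log2 changes were RPL19B -0.61, RPL18B -0.51, HTB1 -0.95, HTA2 0.51, HHF2 0.79, GLK1 0.16, ENO2 0.24, PGK1 0.22, MCM6 -0.72, RFC1 -0.71, RNH203 0.50, RNH70 0.44, RNH1 -0.0084, CAN1 0.38, URA3 0.49, LYP1 0.39, GAL7 -0.54, GAL4 -0.53, GAL1 0.18, SNR38 -0.24, HYR1 0.30, PMA1 0.12, SAP4 -0.57, EIS1 0.22 and TRS23 0.056. In pol2-M644L the log2 changes were HTB2 0.19, HTB1 0.20, HHF1 0.12, PYK2 0.081, TPI1 0.066, DPB2 -0.11, MCM3 0.18, RNH70 -0.075, ADE2 -0.19 and SNR35 -0.089.

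Thinning turned the sign of 8 named genes, none of which passed the threshold, to log2 changes in pol1-L868M RNH202 0.024, in pol3-L612M HHT1 -0.040, RNH202 0.033, RNH203 0.036 and RNH70 0.041, in pol2-M644G RNH1 -0.069 and in pol2-M644L RNH203 0.17 and GAL3 0.0042. The 318 chip alone turned 3, to values in pol2-M644G HHO1 0.0021 and in pol2-M644L RNH70 -0.025 and GAL1 0.00046, and chip as a block turned 4, to values in pol2-M644G HHF2 0.0020 and in pol2-M644L HHF1 0.024, ADE2 -0.0028 and MET17 -0.011.

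By the same rules, leaving out each library in turn kept 257 values of comparisons, moved 6, turned the sign of 7, gained 2 and lost 8 calls. The pooled ratio of pol1-L868M against pol3-L612M ranged from 0.19 to 0.24 over 8 fits. With 1 of these libraries left out, its exact permutation p can no longer go below 0.05 (smallest 0.0571 for 3 against 4). Its loss of the unadjusted threshold in those fits was therefore fixed in advance. Calls in 5 kb bins ranged from 971, without pol2-M644L replicate 2, to 1748 for pol2-M644L and from 949, without pol3-L612M replicate 3, to 1692 for pol1-L868M against pol3-L612M. Gene counts ranged from 0 to 1 for pol2-M644L and for pol2-M644G against pol2-M644L, where YHL050C is the gene concerned. The difference in density near origins ranged from 0.021 to 0.036 for pol1-L868M, passing unadjusted without pol1-L868M replicate 2, from 0.020 to 0.038 for pol3-L612M, 0.0085 to 0.015 for pol2-M644L, and from -0.0099 to 0.0072 for pol1-L868M minus pol3-L612M. The mitochondrial difference ranged from -0.244 to -0.109 for pol1-L868M, passing unadjusted without pol1-L868M replicate 3, and from -0.507 to 0.122 for pol2-M644G minus pol2-M644L. It ranged from -0.877, without pol2-M644L replicate 2, to -0.248, without replicate 1, for pol2-M644L. For pol3-L612M it ranged from -1.06, without pol3-L612M replicate 1, to -0.521, without replicate 2, and leaving out the same libraries gave 0.899 and 0.359 for pol1-L868M minus pol3-L612M. The ribosomal DNA difference ranged from 0.0018 to 0.013 for pol1-L868M, 0.0069 to 0.036 for pol3-L612M, -0.016 to -0.0061 for pol2-M644G, -0.013 to 0.0077 for pol2-M644L, -0.028 to 0.00080 for pol1-L868M minus pol3-L612M and -0.018 to 0.0020 for pol2-M644G minus pol2-M644L. The log2 change of 29 named genes that did not pass crossed 0 when a library was left out. In pol1-L868M the ranges were RNH70 -0.083 to 0.039, TRP1 -0.0014 to 0.13, LYP1 -0.023 to 0.089, GAL1 -0.17 to 0.018, GAL2 -0.0065 to 0.099 and GAL7 -0.060 to 0.11. In pol3-L612M the ranges were HTB1 -0.0017 to 0.21, HHT1 -0.055 to 0.30, HHO1 -0.068 to 0.20, TDH2 -0.037 to 0.47, TDH3 -0.073 to 0.29, PFK1 -0.13 to 0.026, ENO2 -0.13 to 0.32, MCM4 -0.18 to 0.015, PRI1 -0.19 to 0.037, RNH70 -0.084 to 0.042, LYS2 -0.16 to 0.041, ADE2 -0.14 to 0.029, GAL3 -0.17 to 0.0085 and GAL7 -0.046 to 0.18. In pol2-M644G the ranges were HTA2 -0.20 to 0.017 and HHF2 -0.43 to 0.039. In pol2-M644L the ranges were RNH203 -0.34 to 0.016, RNH1 -0.023 to 0.12, RNH70 -0.021 to 0.091, ADE2 -0.052 to 0.13, MET17 -0.048 to 0.16, GAL3 -0.15 to 0.0034 and GAL1 -0.10 to 0.057. Where a mutant was left with 1 library, that library was assumed to vary like the others in edgeR's shared estimate.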

Other observations

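The segments and the grouping of origins below were chosen after their values were seen, and no test was made on them. Origins differed in how far their strand bias moved. The 279 with both flanks covered were split into 3 sets of 93 by the rise in top-strand share that defined them, and the 37 with a sparse flank were left out. The sets had median log2 changes in pol3-L612M of -0.30, -0.64 and -0.77 from the lowest to the highest rise, in pol1-L868M of -0.17, -0.36 and -0.47 and in pol2-M644L of -0.21, -0.38 and -0.45. In pol2-M644G, whose counts defined the rise, the medians were 0.99, 1.35 and 1.42. In pol3-L612M the quartiles of the origins with the highest rise were -0.83 and -0.71.

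A stretch inside NUM1, a gene of nuclear migration with internal repeats (IV 757651 to 758050), held 0 or 1 counts in each POL library and 1 in stationary POL. The mutants held 7.38 ± 3.28 CPM in pol1-L868M (n = 5), 6.75 ± 2.31 in pol3-L612M (n = 3), 7.28 ± 0.723 in pol2-M644G (n = 2) and 9.07 ± 0.171 in pol2-M644L (n = 2), and stationary pol1-L868M held 10.2. An interval between genes of Ty elements, which are repeated in the genome (IV 877426 to 878658), held 6.24 ± 9.39 CPM in POL, from 0 to 19.9. It held 26.4 ± 12.4 in pol1-L868M, 24.1 ± 19.3 in pol3-L612M, 22.2 ± 3.43 in pol2-M644G and 14.3 ± 0.741 in pol2-M644L. Stationary POL and pol1-L868M held 9.23 and 12.6 there. With Nb.BtsI they held 13.9 and 7.57, from 51 and 35 counts in 1 library each. The Nb.BtsI value of POL lies within the 0 to 19.9 of its log-phase RNase H2 libraries, so no direction can be read from it. In the NUM1 stretch Nb.BtsI gave 0 and 2 counts. Mitochondrial counts of the Nb.BtsI libraries lay on the top strand in 33.6% of POL and 32.2% of pol1-L868M counts, against 51.0% ± 1.10 in POL after RNase H2 (n = 4).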
